A study of Nicotiana tabacum with 6 samples.

How the data were processed

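RNA-seq was made from polyadenylated RNA of 6 seedling samples, 3 from the control solution and 3 from the low-nitrogen solution, per the labels' protocols. The deposited values are TPM (reads divided by transcript length and scaled to a common sum per library), rounded to 3 decimals, in 1 table that holds 70985 features and 6 columns, and the columns have equal sums. Per the submitters' processing notes, HISAT2 was used; its version, the counting tool and the genome build are not given in the sources used here. The authors' scaling makes each column a composition, so a rise of abundant genes lowers all others.

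Feature IDs were matched to a table of gene names of the assembly ASM71507v2 (cultivar K326): 54382 IDs (76.6%) matched. Because most entries have no name beyond the ID, 944 of the 41835 tested features (2.26%) had a gene name, and statements on named genes cover that small part. No coordinates are printed, since the build behind the values was not stated. Tobacco carries near-identical gene copies from both ancestral genomes, and reads of such copies may have been split between them in the authors' counting.

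Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, in a model with the group as its single term and empirical Bayes moderation with the trend and robust settings. Features entered with a mean of at least 1 TPM over the 6 samples (41835 features), and p-values were two-sided and adjusted after Benjamini and Hochberg, with a threshold of 0.05. Log2 changes are on the log2(TPM + 1) scale, which understates the change of genes at low levels, and are low nitrogen minus control. The design fixed before the data were examined called for gene lists drawn from product descriptions. The table of names holds none, and of the 48 lists so defined 1 had at least 5 tested members when matched on names, the WRKY factors, which were not called by camera (adjusted p = 0.32) and were called higher by fry (adjusted p = 0.013). The 38 lists used here were therefore assembled from gene names and synonyms after the IDs had been seen and before any test was run; 31 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Fry tests whether a list's genes move on balance 1 way and does not compare them with other genes. Camera with an estimated correlation gave larger p-values even where the estimate lay below the preset, as for ER chaperones (-0.065), phenylpropanoids (-0.0094) and cell cycle genes (4.5e-04). A larger correlation is not why those calls were lost. Photosynthesis genes, with an estimate of -0.022, went from a camera p of 1.9e-19 at the preset to 5.5e-04. A call lost with an estimated correlation thus does not by itself show that members of a list vary together. The estimate lay well above the preset for polyamines (0.48), pathogenesis-related proteins (0.29) and the nitrogen list (0.21), among others.

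Some of the genes named in the text follow a rule fixed beforehand: among called genes whose groups do not overlap, with a mean of at least 5 TPM in the higher group and a gene name in place of a product description, the 8 largest rises and 8 largest falls; then, in each core nitrogen list and each called list, up to 3 members with the lowest adjusted p. All other genes named in the text, from these lists, from lists that were not called or not tested and outside the lists, were chosen after their values were seen. For features without a name, the rule allowed at most 2 that rose and 2 that fell, and those with the largest changes under the same limits are given.

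TPM values of tRNA features gave the value of 1 read per base of length in each library, and every tested feature was then searched for a transcript length at which its 6 values were whole reads, to within 0.15 reads. This held for 40739 of 41835 features (97.4%) and for 0 of 2000 features whose values had been shifted. These reads cover between 88.8% and 89.4% of each library's TPM; they were used for depth, for comparing replicates and for 1 alternative test. Over genes with at least 50 reads, the chi-square per degree of freedom between replicates averaged 1.06 for control replicates 1 and 2 and between 1.12 and 1.39 for the other pairs, where counting error alone gives a value near 1. All 6 libraries were counted as separate replicates because the labels number 3 libraries per group; these values do not show whether they came from separate plants.

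The fit was tested on simulated data: reads were drawn for 40739 features at the real levels and depths with 2% extra spread, and 200 genes were changed. Of 50 genes per size, the fit called 26% at 1.25-fold, 70% at 1.5-fold, 96% at 2-fold and 98% at 4-fold, and 9 of its 154 calls (5.84%) were unchanged genes. Of 20 lists of unchanged genes 0 were called by camera. Each gene was drawn on its own there, so these lists cannot show how camera behaves when members of a list vary together. The 200 changed genes were also far fewer than the 13942 called in the data, so the shares recovered may differ there.

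Alternatives were other pseudocounts (0.1 and 5), filters (none, and a mean of 5 TPM), TMM factors, quantile normalization, rescaling without the 100 highest genes, array weights, moderation with neither the trend nor the robust setting, the replicate number as a block and leaving out each library in turn. A voom fit on the recovered reads was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps.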

Results

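Messenger RNA was profiled in 6 libraries of tobacco (Nicotiana tabacum) seedlings that over-express NtLNRU. Control seedlings (3 libraries) grew in nutrient solution with 10 mM ammonium nitrate and low-nitrogen seedlings (3 libraries) in solution with 0.5 mM, and both were sampled after 3 days. The comparison addresses how these over-expressing seedlings respond to a low nitrogen supply; no wild-type seedlings are among the samples, so the effect of the over-expression itself was not analysed here. No ID carried the name LNRU in the gene names used, so its level is not given. Values were TPM, and the steps between low values gave whole reads for 97.4% of the tested features, with 14460336, 14680139 and 25487646 recovered reads in control replicates 1, 2 and 3 and 16996460, 15176405 and 17694549 in low-nitrogen replicates 1, 2 and 3. At the median recovered transcript length, 1 read corresponded to between 0.030 and 0.052 TPM.

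The first principal component held 71.3% of the variance and separated the groups, with control libraries between -31.2 and -29.7 and low-nitrogen libraries between 30.1 and 31.8. The second component held 8.1% and set low-nitrogen replicate 2, at 20.3, apart from low-nitrogen replicates 1 and 3, at -11.0 and -9.87. Pearson correlations across genes, which are not independent replicates, lay between 0.994 and 0.995 within groups and between 0.979 and 0.980 between them.

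**Figure D1:**
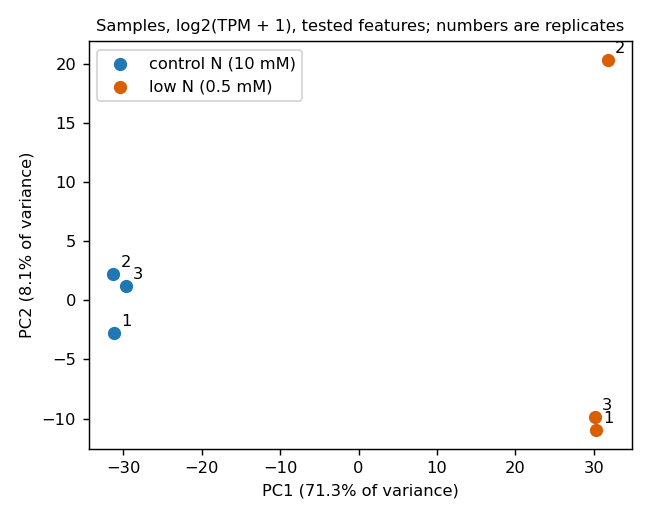
Each point is 1 library (3 per group, replicate number beside it), placed by its score on the first (x axis) and second (y axis) principal component of log2(TPM + 1). The groups lie at opposite ends of the first component, and low-nitrogen replicate 2 lies at 20.3 on the second.

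Under low nitrogen, 9 of 12 tested genes for nitrate uptake and nitrogen assimilation rose, and 24 of 25 tested nuclear genes for photosynthesis fell. Camera at the preset correlation called both lists; with an estimated correlation the adjusted p was 0.17 for the nitrogen list and 0.017 for photosynthesis. The largest rise of a named gene was that of nrt2.2, a high-affinity nitrate transporter, from 2.43 ± 0.16 to 41.1 ± 0.80 TPM (SD, n = 3 each), a 16.9-fold higher mean. Among 41835 tested features, 13942 passed an adjusted p of 0.05 with limma, 6255 higher and 7687 lower in low nitrogen. Of these, 541 also changed at least 2-fold on the log2(TPM + 1) scale, 82 higher and 459 lower. Most changes were small on that scale, which understates the change of genes at low levels. On it, 11989 of the called genes changed by less than 1.5-fold, and their median absolute log2 change was 0.32. Of the 944 tested features with a gene name, 499 were called, 255 higher and 244 lower. The lists hold named genes, so counts within a list are to be read against that share. Camera compared each list with all tested features, of which 33.3% were called, and not with named genes alone. Its p-values are therefore not set against named genes. The groups did not overlap for 46.4% of the tested features, where chance gives 10%. The excess of lower over higher calls turned under TMM factors, with 7158 higher and 6749 lower, and under quantile normalization, with 7326 higher and 6457 lower, whereas genes that changed at least 2-fold were mostly lower under every setting tried. The labels do not say whether the replicates came from separate plants or cultures, so the p-values measure only the spread between these libraries, which may be technical.

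Of the 12 tested genes for nitrate uptake and nitrogen assimilation, 9 rose, 2 fell and 1 did not pass, and the same numbers held when adjusted over the list alone. After nrt2.2, the largest rise was that of NIA1 (LOC107823732), which encodes nitrate reductase, from 22.1 ± 1.1 to 51.01 ± 0.92 TPM (SD, n = 3), a log2 change of 1.17 ± 0.04 (SE). The nitrate reductase gene NIA2 rose from 36.2 to 56.1 TPM. The nitrate transporter genes NtNRT1.1-s and NtNRT1.1-t rose by 0.72 and 0.40 on the log2 scale, while NtNRT1.2-s stood at 69.1 TPM in control and 67.4 TPM in low nitrogen (adjusted p = 0.44). The nitrite reductase genes nii2 and nii4 rose by 0.20 and 0.13. The members that fell were Gln1-5, a cytosolic glutamine synthetase gene, from 1420 ± 28 to 1206 ± 13 TPM, and the glutamate dehydrogenase gene gdh1, by 0.33 on the log2 scale. The glutamine synthetase gene Gln1-3 rose by 0.21. The list was called higher by camera (adjusted p = 2.9e-04), and this call was lost with an estimated correlation (adjusted p = 0.17).

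**Figure D2:**
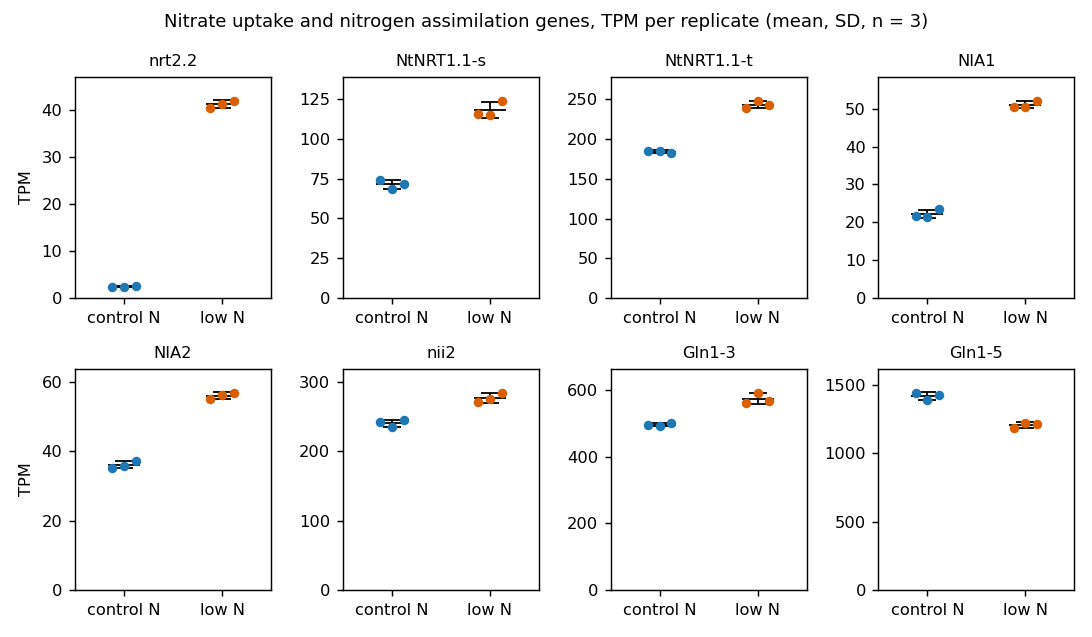
TPM (y axis, from 0) of 8 nitrogen genes in the 3 control and 3 low-nitrogen libraries (x axis); points are libraries, the long bar is the group mean and the whiskers are 1 SD. nrt2.2 moved from 2.43 to 41.1 TPM, whereas Gln1-5 moved from 1420 to 1206 TPM.

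Phosphate transporters and ER chaperones were among the other large rises. NtPT4 rose from 20.1 ± 1.4 to 35.1 ± 0.76 TPM and NtPT3 from 50.7 ± 1.2 to 87.2 ± 2.2 TPM (SD, n = 3), while NtPT2 was at 64.4 and 60.3 TPM (adjusted p = 0.052). All 7 tested ER chaperone genes rose. BIP4, which encodes a luminal binding protein of the endoplasmic reticulum, changed most, from 24.996 ± 1.533 to 44.0 ± 2.8 TPM, followed by BIP8 and BIP5 at log2 changes of 0.56 and 0.49. Camera called this list higher (adjusted p = 4.0e-05; adjusted p = 0.077 with an estimated correlation). The remaining 3 of the 8 largest rises were NCAPP1, a gene of the protein trafficking pathway between cells, at a log2 change of 0.85, CYP74D3, a divinyl ether synthase gene, at 0.85, and the expansin gene EXPA6 at 0.76.

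Of 25 tested nuclear genes for photosynthesis, 24 fell and none rose, with a median log2 change of -1.13. Their levels were modest in control already: the median of the members was 16.6 TPM in control and 7.06 TPM in low nitrogen. For the nicotine list, given below, the median in control was 106.7 TPM. Among the 8 largest falls of named genes with a mean of at least 5 TPM in the higher group were 6 from this list: Rca (LOC107798594), which encodes rubisco activase, fell by 1.76, petC2, a Rieske iron-sulphur protein gene, by 1.70, PsbQ (LOC107816469) and psbQ (LOC107767928), genes of the oxygen-evolving complex, by 1.61 and 1.44, GAPB, a chloroplast glyceraldehyde phosphate dehydrogenase gene, by 1.53, and CAB21, a chlorophyll-binding protein gene, by 1.40. CAB21 dropped from 70.6 ± 1.5 to 26.1 ± 1.0 TPM (SD, n = 3; adjusted p = 3.8e-09). The member that did not pass was FNR, a ferredoxin reductase gene, at 172.5 ± 3.3 and 170.9 ± 3.0 TPM, whose small change had the opposite sign with TMM factors. Camera called the list lower (adjusted p = 6.0e-18), and it was the 1 list still called with an estimated correlation (adjusted p = 0.017). The other 2 of these 8 falls were those of TCP4, a transcription factor gene, by 1.75, and BCH2, a carotene hydroxylase gene, by 1.32.

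Camera also called 3 other lists of plastid function lower, and none of these calls held with an estimated correlation. Of 15 genes for tetrapyrrole and chlorophyll synthesis 10 fell, among them chlP by 0.47 and POR2 by 0.76, and of 8 plastid ribosomal and elongation factor genes 7 fell, among them CL12 by 0.64. Of 19 genes for carotenoids and plastid isoprenoids, BCH2 among them, 11 fell and 1 rose. Camera adjusted p-values for these 3 lists were 0.0013, 9.5e-04 and 0.0013, and with an estimated correlation the adjusted p was 0.077 for each.

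Genes of nicotine and polyamine synthesis fell. Of 18 tested genes for nicotine synthesis, regulation and transport 15 fell and none rose. ODC2, which encodes ornithine decarboxylase, fell from 480.4 ± 4.5 to 308.9 ± 7.4 TPM (SD, n = 3), and the putrescine N-methyltransferase genes PMT1 and PMT2 fell by 0.43 and 0.74 on the log2 scale. The regulator gene ERF189 was at 3.49 and 3.18 TPM (adjusted p = 0.53). The nicotine N-demethylase gene CYP82E5 fell from 173.4 to 120.9 TPM. Of 5 polyamine genes 4 fell, with AdoMetDC and ADC1 each lower by 0.43. Camera called both lists lower (adjusted p = 4.8e-06 for nicotine and 0.0036 for polyamines), and neither call held with an estimated correlation (adjusted p = 0.077 and 0.25). ODC2 is a member of both lists.

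The lists of pathogenesis-related proteins, jasmonate genes and ethylene genes were called lower by camera, and none of these calls held with an estimated correlation. Of 14 tested genes for pathogenesis-related proteins 10 fell and 3 rose. AP24, which encodes osmotin, dropped from 442.8 ± 8.0 to 201.5 ± 1.4 TPM, and PI-Ib and PI-Ia, which encode proteinase inhibitors, from 696.1 ± 9.3 to 308.5 ± 13.6 TPM and from 967.1 ± 2.9 to 510.5 ± 19.4 TPM (SD, n = 3). The risers PR-1B, PR-1C and PR-P had means no higher than 6.45 TPM in either group, and without low-nitrogen replicate 1 they were not called (adjusted p = 0.13, 0.084 and 0.090). Of 8 jasmonate genes 5 fell, among them the oxophytodienoate reductase genes opr2 by 0.34 and OPR1 by 0.53, and of 21 ethylene and ERF genes 9 fell and 1 rose, among the falls EREBP-1 by 0.57. Camera adjusted p-values were 0.0015, 0.032 and 0.041, and with an estimated correlation the adjusted p-values were 0.29, 0.19 and 0.16. The ethylene list was no longer called without control replicate 1, low-nitrogen replicate 1 or low-nitrogen replicate 2 (camera adjusted p = 0.071, 0.064 and 0.053), nor was the jasmonate list without low-nitrogen replicate 2 (0.052).

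**Figure D3:**
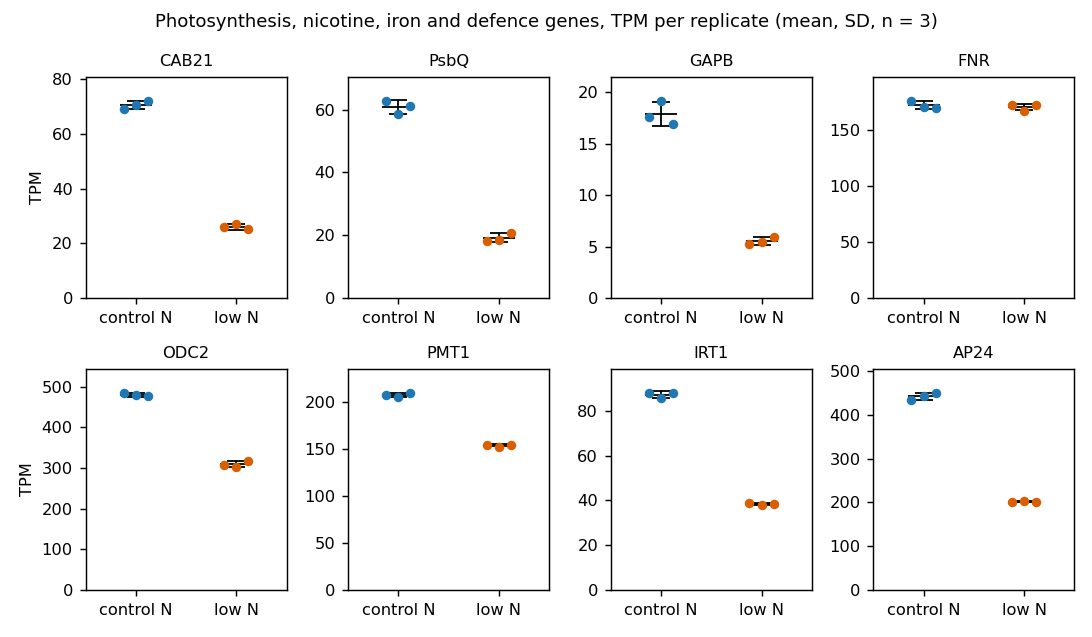
TPM (y axis, from 0) of photosynthesis genes (CAB21, PsbQ, GAPB, FNR), nicotine genes (ODC2, PMT1), the iron transporter gene IRT1 and the osmotin gene AP24 in the 3 control and 3 low-nitrogen libraries (x axis); points are libraries, the long bar is the group mean and the whiskers are 1 SD. All but FNR were lower in the low-nitrogen libraries.

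Of 12 genes for iron, zinc and other metals 5 fell and 1 rose. IRT1, which encodes an iron transporter, fell from 87.3 ± 1.4 to 38.5 ± 0.51 TPM, the nicotianamine synthase gene NtNAS2 from 106.7 ± 0.63 to 58.6 ± 2.6 TPM, and NtYSL1 by 0.54 on the log2 scale. The ferritin gene FER1 rose from 60.1 to 71.5 TPM. The list was called lower (camera adjusted p = 0.038), with an adjusted p of 0.36 when the correlation was estimated. Without control replicate 1, low-nitrogen replicate 1 or low-nitrogen replicate 2 it was not called (adjusted p = 0.051, 0.052 and 0.053).

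The remaining lists that camera called higher moved by small amounts, and none of these calls held with an estimated correlation. Of 26 genes for phenylpropanoids and lignin 21 rose and none fell, with a median log2 change of 0.17 and the largest support for CYP73A27, a cinnamate hydroxylase gene, at 0.54. Of 42 cell cycle and chromatin genes 20 rose and 4 fell; the histone gene H2B1 rose by 0.41, while the histone gene H1c fell by 0.33 and A10 by 0.35. Of 26 genes for cytosolic ribosomal proteins and translation factors 15 rose, RL2 by 0.42 and RPL3A by 0.38, and 2 fell, NTTCTP among them by 0.27. Camera adjusted p-values were 2.2e-06, 7.4e-04 and 0.0013, and with an estimated correlation the adjusted p-values were 0.065, 0.077 and 0.16. Of 14 genes for senescence and proteases 9 rose, with CP6, a cysteine protease gene, at a log2 change of 0.25 (camera adjusted p = 9.5e-04; adjusted p = 0.15 with an estimated correlation). Of 9 wall-loosening genes 4 rose and 1 fell, EXGT-N2 rising by 0.31, and of 8 aquaporin genes 5 rose and 1 fell. RT-TIP, a tonoplast aquaporin gene, rose from 541.7 ± 1.6 to 855.7 ± 15.0 TPM and MIP fell by 0.24. Camera adjusted p-values for wall loosening and aquaporins were 0.015 and 0.027, and with an estimated correlation the adjusted p-values were 0.15 and 0.16. The ribosomal, wall-loosening and aquaporin lists were not called after quantile normalization (adjusted p = 0.065, 0.076 and 0.13).

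**Figure D4:**
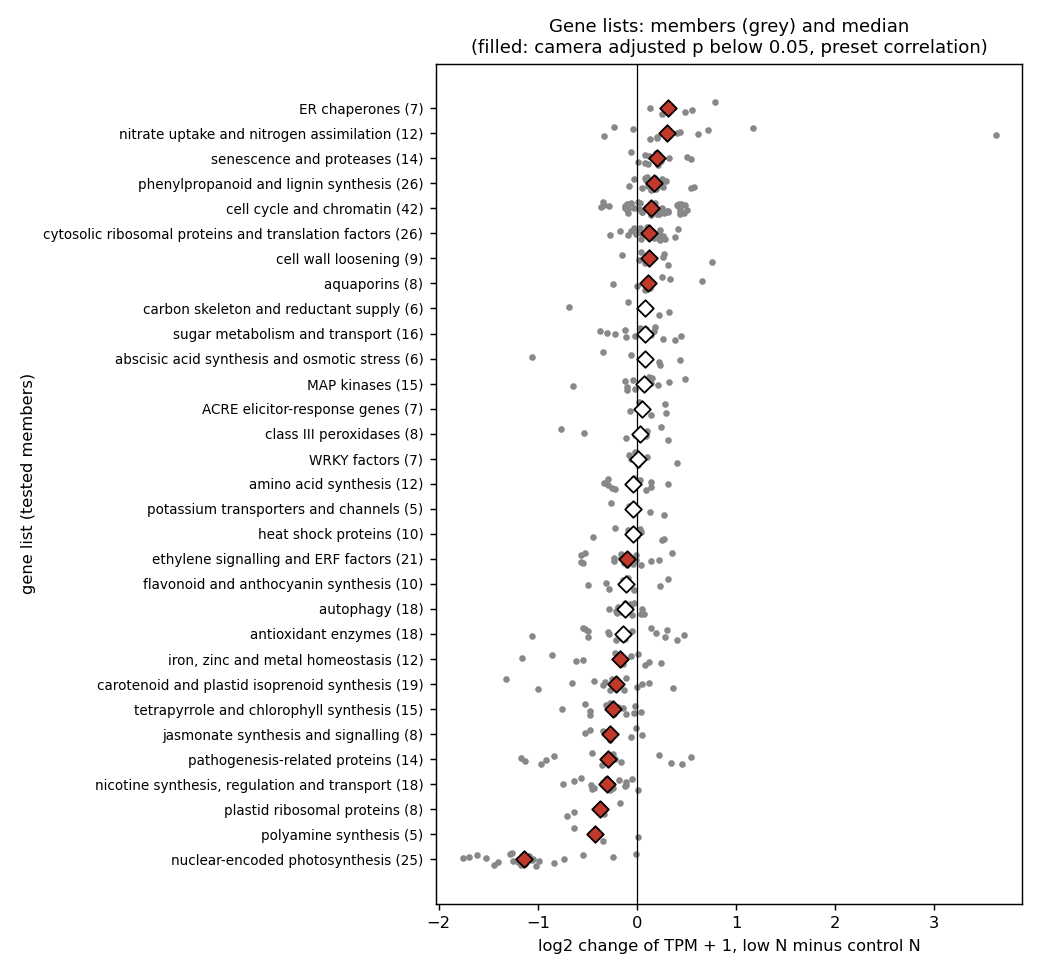
For 31 gene lists (y axis, number of tested members in brackets), grey points are the log2 changes of the members and diamonds their median (x axis, log2 change of TPM + 1, low nitrogen minus control). Filled diamonds mark the 18 lists called by camera at the preset correlation, 8 higher and 10 lower, of which photosynthesis, at a median of -1.13, was the 1 list still called with an estimated correlation.

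The other core lists were not called by camera. Of 6 genes that supply carbon skeletons and reductant, cit1, a citrate synthase gene, and PEPC rose by 0.33 and 0.22, and gMDH, a malate dehydrogenase gene, fell by 0.68 (camera adjusted p = 0.45). Of 12 genes for amino acid synthesis 3 rose, NtGAD1 among them by 0.32, and 4 fell, oas1 by 0.29 and SuRB by 0.34 among them (camera adjusted p = 0.67), and fry, which does not compare a list with other genes, called this list lower (adjusted p = 0.0093).

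Among features without a gene name, LOC107808057 rose from 18.7 ± 0.29 to 139.9 ± 4.0 TPM, and LOC107826782 was listed at 0 in all control libraries and at 11.3 ± 0.66 TPM in low nitrogen (SD, n = 3). LOC107793843 fell from 40.5 ± 1.2 to 0.041 ± 0.036 TPM and LOC107800215 from 20.01 ± 1.3 to 0.030 ± 0.051 TPM, levels in low nitrogen that correspond to no more than a few reads. LOC107826782, LOC107793843 and LOC107800215 were among 14 features with a mean of at least 5 TPM in 1 group and at most 0.2 TPM in the other.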

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

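The voom fit was chosen after seeing the data. The count of changed genes (13942) stayed between 11008 and 15434 in all settings; leaving out 1 library gave between 11437 and 12280, with fewer samples in the fit. The count of at least 2-fold changes (541) depended on the pseudocount and the filter. It was 933 at a pseudocount of 0.1 (172 higher, 761 lower), 165 at a pseudocount of 5 (25 higher, 140 lower), 323 with a mean TPM of at least 5 (261 lower), where fewer genes are tested. It was 996 with voom on recovered reads (181 higher, 815 lower), which changes several choices at once, so this move is not put down to 1 of them. A larger pseudocount shrinks the log2 changes of low genes by construction. Leaving out 1 library gave between 523 and 567.

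Of the 18 called lists, 1 was called with an estimated correlation and all 18 were among the 27 called by fry. Leaving out 1 library gave between 15 and 18 lists. Besides the losses given with each list, the aquaporin and ethylene lists were not called without a filter (adjusted p = 0.075 and 0.063) nor the jasmonate list at a mean TPM of at least 5 (0.053). None of the 18 called lists and no called gene named in the text changed direction in any setting. Lists that were not called by camera were not followed over the settings. Among them potassium transport, abscisic acid and heat shock pointed upward with camera and downward with fry. All but 7 of the 101 named genes kept their side of the threshold in every setting that tested them. PR-1B also lost its call without control replicate 1 or 3 or low-nitrogen replicate 2 (adjusted p between 0.11 and 0.12), PR-1C without control replicate 1 or low-nitrogen replicate 2 (0.071 and 0.059), PR-P without control replicate 2 or 3 (0.090 and 0.078), GA2ox2 without control replicate 2 or low-nitrogen replicate 1 (0.075 and 0.070), and atp9 without any 1 of 4 libraries, control replicates 2 and 3 and low-nitrogen replicates 1 and 2 (0.12, 0.086, 0.087 and 0.16). PR-1B, PR-P and atp9 also missed the threshold without a filter or with neither trend nor robust moderation, as did nii4 in the latter (adjusted p = 0.077), and atp9 at a pseudocount of 0.1 (0.052) and a mean TPM of at least 5 (0.052). NtPT2, not called, passed in 6 settings with adjusted p between 0.011 and 0.046.

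No pairing by replicate number was seen: deviations of same-numbered samples correlated at 0.015, -0.005 and -0.014. A shared batch could be hidden by counting error, so its absence is not shown. In control genes with 100 to 300 reads counting error was 8.02% and the spread beyond it 1.72%. With the replicate number as a block, 13252 genes, 542 at least 2-fold and 17 lists were called; the metal list was not (adjusted p = 0.069), and no other list or named gene changed its call. The median log2 change of all tested genes was -0.022 and moved to -0.031 at the lowest and 0.016 at the highest under other scalings of the TPM columns. Depth limits the low end: 1 read was worth up to 0.052 TPM at the median length.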

Other observations

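The tests of the photosynthesis fall, of the genes nearly absent from 1 group, of the replicate spread and of the other splits were chosen after the results they concern were seen.

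Several further lists were not called by camera. Of 18 genes for antioxidant enzymes 11 fell and 5 rose: the stress-induced gene par fell from 271.0 ± 4.6 to 130.1 ± 5.9 TPM and the catalase genes cat3 and CAT-1 by 0.50 and 0.28 on the log2 scale, while the alternative oxidase genes aox and AOX rose by 0.48 and 0.41 (camera adjusted p = 0.15). Of 16 genes for sugar metabolism 4 rose, the hexose transporter gene MST1 by 0.45 and the sucrose phosphate synthase gene sps by 0.38 among them, and 3 fell (0.22). Of 6 genes for abscisic acid and osmotic stress 3 rose, P5CS by 0.44 among them, and 2 fell, the galactinol synthase gene GolS by 1.06 (0.81). Of 18 autophagy genes 3 fell and none rose (0.11), and with p-values adjusted over the list alone 0 passed. Of 10 flavonoid genes 2 rose and 2 fell (0.50), of 8 class III peroxidases 2 rose and 3 fell (0.81), of 10 heat shock genes 2 rose and 1 fell (0.99), of 15 MAP kinase genes 4 rose and 1 fell (0.26), of 7 ACRE genes 2 rose (0.15), of 7 WRKY genes 1 rose (0.45), and of 5 potassium transport genes 1 rose and 1 fell (0.84). The median and the mean log2 change differed in sign for the lists of carbon skeletons, potassium transport, abscisic acid and class III peroxidases, and for heat shock both were below 0 while camera pointed upward.

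Lists with fewer than 5 tested members gave these values. Of 4 KNOX genes, which act in shoot meristems, 3 fell, among them NTH201 by 0.36. Of 3 gibberellin genes 1 fell, GA2ox2 by 0.36. Of 11 floral and pollen markers 0 reached the filter. Of the 98 plastid-encoded features 1 reached it and did not pass (ycf3, adjusted p = 0.99). Of the 156 mitochondrial ones 4 reached it and 3 rose, atp9 from 19.9 to 28.9 TPM among them. In this polyadenylated RNA plastid features held 0.0017% of TPM in control and 0.0014% in low nitrogen. Mitochondrial features held 0.0054% and 0.0071%. The few that were tested therefore say little about organelle transcripts as a whole. The median control level was 106.7 TPM for the nicotine list and 16.6 TPM for the photosynthesis list.

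For the fall of the nuclear photosynthesis genes 2 narrow explanations were checked. If a smaller share of green tissue in the low-nitrogen samples had lowered every member alike, the members would have fallen by 1 factor, but their log2 changes at a pseudocount of 0.1 ran from -2.24 to -0.01 and differed far beyond their errors (chi-square per degree of freedom 86.4). The end at -0.01 is FNR, already seen not to pass, and the chi-square was not computed without it. These values argue against 1 factor common to all members, FNR included, and not against a change in tissue makeup as such. Scaling of the TPM columns would need a median near 0 under another scaling, and the median nearest to 0 was -1.11. Other scalings of the TPM columns moved the median of all tested genes only to between -0.031 and 0.016. They could thus not have removed a fall of this size, and the result covers the scalings tried alone. A smaller green share with members that are also expressed in other tissues may still account for part of the fall, and so may the nitrogen supply itself; neither was tested.

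For 14 genes the mean was at least 5 TPM in 1 group and at most 0.2 TPM in the other, 13 of them lost and 1 gained in low nitrogen, and none of the 14 has a gene name. The named gene cpr2, a cytochrome P450 reductase gene, moved the same way at a lower level, from 3.64 ± 0.14 to 0.049 ± 0.047 TPM. Too few reads cannot be the reason, since at least 29.7 reads were expected in each library of the group near 0 and at most 4 were seen. A chromosome segment that differs between the plants of the groups may be a cause. Neighbouring tested genes had a median log2 change of 0.09 in the gene's direction, and 4 of 36 moved by at least 1 that way. Among all tested features 1.29% were called with a change of at least 2-fold in either direction. The neighbours needed no call, and another of the 14 genes could count as a neighbour, so these shares are not alike. A median over all neighbours would miss a segment behind a few genes. Only 9 of the 14 genes (64.3%) could be placed. The check is therefore void and the explanation stays open, as do the treatment and differences at single genes between seed lots or lines. The labels do not say whether both groups came from 1 seed lot or line, and a difference of that kind would enter every comparison between the groups.

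The replicates differed by little more than counting error: in genes with 1000 to 3000 reads the spread beyond it was 1.502% in control and 2.46% in low nitrogen. Libraries made from 1 pool of plants or 1 RNA sample per group may give such a spread, and so may many plants per library; these cannot be told apart here, because the labels do not say how the replicates were made. With a spread this small, changes well under 1.5-fold were called.

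The 6 samples can be split into 3 against 3 in 10 ways, too few for a share under 0.05. In 1 of the 10, the real one, 13942 genes, 541 genes at least 2-fold and 18 lists were called. The other splits gave 0 genes, 0 genes at least 2-fold and between 2 and 4 lists. Each of them puts libraries of both groups on both sides, so the difference between the groups counts as spread within a side. Few gene calls were thus fixed in advance, and no conclusion on chance is drawn from them.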
